A study of Rattus norvegicus with 41 samples.

How the data were processed

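Colon tissue of newly weaned male Sprague-Dawley rats was measured on 41 Agilent whole rat genome arrays, each with 2 colours. Rats were conventionally raised (CV) or kept germ-free in a gnotobiotic isolator (GF), and were fed a basal diet or a diet with a digestion-resistant carbohydrate for 28 days. Per the labels, tissue RNA (200 ng) and a common reference (500 ng of colon RNA from colony rats) were amplified and labelled with the Agilent low-input kit. The reference was hybridised with every tissue sample.

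The deposited scanner files of Agilent Feature Extraction gave mean signals and local background medians per spot as intensity units in both channels, per the file headers. Version 9.5.1.1 wrote the files of the 23 CV arrays and version 9.5.3.1 those of the 18 GF arrays. The CV arrays lay on 6 slides and the GF arrays on 5, and each of 2 scan sessions held a single colonisation status. The deposited processed signals are also intensity values, which the authors' scanner software had background-subtracted, detrended and dye-normalised. The deposited series matrix holds log2 ratios, for which the authors named limma 3.4.4. Recomputed log2 ratios of red over green, after loess without background correction, had a correlation of 1 with the deposited log2 values on every array and a slope of 1. The base and direction of the deposited log2 values were taken from this comparison, since the authors' notes state neither.

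The labels and the labelling protocol disagree on which dye carried the reference. The channel that varied less between arrays was taken as the reference. The red channel had the lower standard deviation in 96.3% of 22884 probes among CV arrays and in 95.7% among GF arrays, against 97.6% and 97% in the processed signals. Red was therefore used as the reference and green as the tissue, and all ratios are tissue over reference.

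Values were made with R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and statmod (version 1.5.0). Mean signals were background-corrected with normexp and an offset of 50. Ratios were loess-normalised within each array with a weight of 0 for control spots, and no scaling between arrays was applied. Each array held 45018 spots, of which 43379 were probe spots of 41012 unique probes. Control spots and values marked as outlying by the scanner software (0.395%) were left out, and spots of one probe were averaged. A probe was kept when the tissue channel was well above background in at least 50% of the arrays of at least 1 group, which 31200 probes met. The brightest probe stood for each gene, which left 26607 features, here called genes. Of these, 12873 had a gene symbol and 13734 a provisional name or none. Several probes had passed for 3161 genes. Missing values made up 0.022% of the tested values.

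One limma model with 7 group means was fitted to all 41 arrays with 34 residual degrees of freedom. The comparisons numbered 13: GF against CV on each of 3 shared diets, each carbohydrate against basal within a status, the difference of the diet effect between GF and CV (interaction) for konjac and for RS, and each pair of carbohydrates in CV rats. All tests were 2-sided. P values were adjusted with Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. A total of 35 gene lists was fixed in advance and tested with camera (limma) at a preset correlation of 0.01, with at least 4 measured members, adjusted over the lists of a comparison. Camera was also run with an estimated correlation. Similarity of diet effects was described by correlations over genes for 6 pairs of comparisons. The 3 CV diets shared a control group, so the correlations were set beside 100 simulated draws with no diet effect.

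The 41 arrays limit the precision of every value, and signal differed between the sessions as given with the results. The method was tested on simulated data with 26607 genes, 50 of them changed at each size. At a true 1.5-fold difference, 88% were called for GF konjac against GF basal, 96% for CV inulin against CV basal, 92% for GF against CV on the basal diet and 72% for the konjac interaction. Of the unchanged genes, 5 to 13 were called per comparison. At a true 2-fold difference 94% to 100% were called. The simulated noise was independent between genes and arrays, with no slides and no differences in tissue make-up, so these rates may not hold for the real arrays. When the real arrays were regrouped at random, up to 286 genes were called for GF konjac against GF basal. For CV inulin against CV basal the highest such count was 94, and for CV konjac against CV basal 3192.

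Named genes followed a rule. It took up to 8 named genes in each direction with the largest difference among those past the threshold that kept their sign when any one array of the compared groups was left out, and up to 4 in each direction for GF against CV on konjac and RS and for pairs of carbohydrates. From each list it took up to 4 members past the threshold with the smallest p. From a list called by camera with no such member, it took the 2 with the smallest p for their values. Where under 4 genes passed in a comparison, the 3 named genes with the smallest p were taken for their values. Genes with provisional names were counted and not named. The text prints only part of these. For GF against CV on the basal diet it gives 2 members per list, for the konjac and RS diets the first part alone, and list members given for their values appear only in comparisons of a carbohydrate with its basal diet. The rest were left out, most of them for length. Where a gene was not well above background in one group, a lower bound of its fold was computed against the floor of the tissue channel alone. It is given where it lies below the fold of the ratios, and otherwise no size is given. No such check was made for the interactions.

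The groups, comparisons, lists, rule, thresholds and first set of alternatives were chosen before the data were examined. That set covered no background correction, the scanner software's processed signals with and without quantile normalisation, the deposited log2 values, the tissue channel alone, 2 other filters, the mean of a gene's probes, trended and robust moderation, array weights, scaling of average intensities between arrays (Aquantile, which leaves ratios as they are), the compared groups alone, slide as a fixed or random block, the replicate number as a block, a fold minimum of 1.5, an estimated correlation between genes, correlations over called genes alone, and each array left out in turn. Scan date as a batch was not run, because each session held one colonisation status.

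Other alternatives were chosen after seeing the data. On 8 arrays, 3 to 17 spots far below their local background displaced the normexp fit. Its fitted width was 87.9 to 841 on these arrays and at most 32.1 on the other 33. Ratios on the 8 arrays were shrunken, with a median size of 0.01 to 0.06 (log2) against 0.09 to 0.18 elsewhere, and 0.12 to 0.17 once spots over 20 units below background were left out. The values reported keep the background correction chosen before the data were examined. Leaving out those spots, doing so with equal scaling between arrays, and leaving out the 8 arrays were added as alternatives. A colon position score, a smooth muscle score and a clock gene score were each added as a covariate.

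Among CV arrays the replicate number is the slide number. Replicate numbers were not used as pairs: 18 of 51 same-numbered pairs of arrays correlated above 0.1 after group means were removed, and 7 of 41 arrays correlated best with an array of their own number. Among GF groups, same-numbered arrays correlated at 0.131 (basal and konjac), 0.07 (basal and RS) and 0.056 (konjac and RS) on average. Arrays of other numbers gave -0.026, -0.014 and -0.011. The clock list mean was -0.35, -0.36 and -0.46 in GF basal 1, GF konjac 1 and GF RS 1. In replicate 6 of these groups it was 0.25, 0.23 and 0.28. GF arrays thus followed their replicate order in part, and the reported fit has no term for it.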

Results

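Gene expression in rat colon was measured on 41 arrays, 1 per rat, as the ratio of tissue signal to a common colon reference. Conventionally raised (CV) rats received a basal diet (n = 6), inulin (n = 5), konjac (n = 6) or resistant starch, RS (n = 6). Germ-free (GF) rats received the basal diet (n = 6), konjac (n = 6) or RS (n = 6). Inulin, konjac glucomannan and resistant starch escape digestion in the small intestine and reach the colon, where bacteria ferment them. Values are log2 ratios, differences carry the standard error (SE) of the limma model, and group means carry the standard deviation (SD).

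Median tissue signal per array was 45.7 to 64.6 intensity units on CV arrays and 280 to 334 on GF arrays. Reference signal was 116 to 144 and 404 to 461. Between 63.2% and 71.2% of probes on CV arrays and between 65.7% and 77.5% on GF arrays were well above background. GF and CV arrays were scanned in separate sessions on separate slides, so colonisation status and session cannot be told apart, and no value within one session exists for that comparison. On 8 arrays (CV RS 1, 4 and 6, CV inulin 2 and 5, CV konjac 5, GF konjac 2 and GF RS 3) the background fit was displaced and ratios were shrunken. The number of arrays limits the precision of all values.

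The comparison of GF with CV rats on the basal diet asked how the colon differs when no bacteria are present. Fabp1, the liver-type fatty acid binding protein of absorptive cells, was higher in GF rats by 4.27 (SE 0.70), at 2.40 ± 0.37 (SD, n = 6) against -1.88 ± 1.70 (SD, n = 6). Nts, which encodes the gut peptide neurotensin, was higher, at 4.75 ± 0.28 against -0.24 ± 0.09. The CV arrays were not well above background for Nts, so the size of its difference was not measured. Ogn, a proteoglycan of the extracellular matrix, was lower by 2.63 (SE 0.17), at -2.33 ± 0.13 against 0.31 ± 0.30. Muscle and matrix genes fell together, and many genes of xenobiotic metabolism rose.

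Among 26607 genes, 12864 (48.3%) passed an adjusted p of 0.05 with limma, 6085 higher and 6779 lower in GF rats. Of these, 2357 differed at least 1.5-fold. Other large rises were those of Cyp4f1, a fatty acid hydroxylase (4.21, SE 1.12), the transcription factor Osr2 (3.70, SE 0.19), the neutrophil defensin RatNP-3b (3.66, SE 0.29), the sulfate transporter Slc13a1 (3.62, SE 0.23) and the steroid dehydrogenase Hsd17b6 (3.33, SE 0.49). The Paneth-cell-type defensin Defa24 was higher too, by a size that was not measured, since its CV arrays were not well above background. Large falls were those of the beta globins Hbb (-3.87, SE 0.39) and Hbb-b1 (-2.32, SE 0.39), the mitochondrial ribosomal gene Mrpl43 (-2.75, SE 0.18), intestinal alkaline phosphatase Alpi (-2.38, SE 0.20) and the protease inhibitor Serpina3n (-2.25, SE 0.34). Each of these genes lay beyond all 6 CV arrays in 6 of 6 GF arrays. The MHC class II gene RT1-Bb (-3.05, SE 1.19, adjusted p = 0.0318) did so in 4 of 6 arrays, and the fatty acid desaturase Scd (-1.97, SE 0.71, adjusted p = 0.0207) in 1 of 6. RT1-Bb lost its call with the scanner software's processed signals (adjusted p = 0.0734), with the tissue channel alone (0.175) and without any of CV basal 1, 2, 4 and 6 and GF basal 2, 3, 4 and 6 (up to 0.0752 without GF basal 3). The Scd call was lost with the processed signals (adjusted p = 0.0535), without CV basal 1 (0.0662) and without CV basal 4 (0.0528). On genome build rn3 the Nts probe lies on chromosome 7 at 40495070 to 40495129, the Fabp1 probe on chromosome 4 at 104659731 to 104660400 and the Ogn probe on chromosome 17 at 20988620 to 20988679.

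Of 25 measured smooth muscle genes 24 fell and 0 rose, with a median of -0.97. They included the actin-binding gene Tagln (-1.87) and the tropomyosin Tpm2 (-1.70), and with the tissue channel alone Tagln differed by -0.62. The list passed with camera at adjusted p = 7.07e-18, but did not pass with an estimated correlation (adjusted p = 0.124). Of 29 fibroblast and matrix genes 28 fell, with a median of -1.07, among them the collagen-binding gene Sparc (-1.90; -0.61 with the tissue channel alone). That list passed at adjusted p = 4.64e-15, and gave adjusted p = 0.232 with an estimated correlation. Xenobiotic metabolism had 27 of 52 genes higher and 5 lower (adjusted p = 0.000374; adjusted p = 0.339 with an estimated correlation). The cytochrome Cyp3a18 rose by 2.21 and the glutathione transferase Gstm3 by 0.60. Nutrient and bile acid transporters had 11 of 25 higher and 3 lower, with 16 passing when adjusted over the list alone. This list includes Nr1h4, the bile acid receptor FXR, which rose by 0.90, and Alpi, which fell. It passed at adjusted p = 0.0118 and at 0.0465 with an estimated correlation, and lost the call with processed signals (0.0637) and with the tissue channel alone (0.179).

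Enteric neuron and glia genes fell in 14 of 27 cases and rose in 2 (adjusted p = 0.00347; adjusted p = 0.802 with an estimated correlation), among them the neurofilament-type gene Prph (-0.85) and Uchl1 (-0.80, but 0.12 with the tissue channel alone). Macrophage and dendritic genes had 11 of 22 lower and 1 higher, with the scavenger receptor Msr1 at -0.68 and Ms4a7 at -1.47. Mucus and goblet cell genes had 14 of 32 lower and 1 higher, including the glycosyltransferase St6galnac1 (-1.14) and Creb3l1 (-1.16, but 0.46 with the tissue channel alone). Endothelial genes had 9 of 18 lower and 1 higher, including Emcn (-0.41) and Vwf (-0.47, but 0.04 with the tissue channel alone, and opposite in 1 other probe). These 3 lists each had adjusted p = 0.042 with camera. With an estimated correlation the adjusted p was 0.839 for macrophages and 0.80 for the other pair. Red blood cell genes had 6 of 8 lower (adjusted p = 0.0494; adjusted p = 0.80 with an estimated correlation), among them Bpgm at -0.37. With the tissue channel alone the macrophage list gave adjusted p = 0.257, mucus 0.803, endothelium 0.535 and red cells 0.462. Adjusted over the list alone, 24 smooth muscle, 29 fibroblast, 34 xenobiotic, 16 neuron, 13 macrophage, 15 mucus, 10 endothelial and 7 red cell genes passed.

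The other 26 lists did not pass, although single members did. Of 33 type I interferon genes 14 rose and 4 fell (list adjusted p = 0.0923), with the antiviral Mx2 at 1.44 and Rig1 at -0.38, which was 0.72 with the tissue channel alone. Of 30 enteroendocrine genes 10 rose and 6 fell (list adjusted p = 0.0918), with the hormone secretin, Sct, at 1.41. Cholesterol synthesis had 5 of 25 higher and 1 lower (list adjusted p = 0.0558), with Hsd17b7 at 0.48 and Mvk at 0.34, which was -0.18 with the tissue channel alone. Cell cycle genes had 10 of 42 lower and 2 higher, with Cdc25b at -0.53 and Prc1 at -0.63 (-0.19, adjusted p = 0.188, with the tissue channel alone). Ion and water transport had 9 of 35 higher and 7 lower, with the sodium channel subunit Scnn1g at 2.26 and the water channel Aqp3 at -1.26. Of 15 antimicrobial genes 4 rose and 2 fell, with S100a9 at 0.90 and the immunoglobulin transporter Pigr at -1.18 (-0.19, adjusted p = 0.303, with the tissue channel alone). Adjusted over the list alone, 20 interferon, 16 enteroendocrine, 5 cholesterol, 11 cell cycle, 16 ion and water and 6 antimicrobial genes passed.

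Among immune lists, T and NK cell markers had 5 of 28 higher and 2 lower, with Cd3g at 1.72 and Icos at -0.48, which was 0.45 with the tissue channel alone. B and plasma cell markers had 1 of 15 higher and 4 lower, with the immunoglobulin joining chain Jchain at -1.73 (-0.42, adjusted p = 0.382, with the tissue channel alone) and Tnfrsf17 at -1.14. Of 17 mast cell and eosinophil markers 7 rose and 3 fell, with the IgE receptor chain Fcer1a at least 2.62-fold higher and Alox15 at -1.10 (-0.17, adjusted p = 0.229, with the tissue channel alone). Of 23 cytokine genes 2 rose and 6 fell, with the interleukin 1 antagonist Il1rn at 1.20 and Il1b at -0.59. Of 23 Toll-like receptor and NF-kB genes 4 rose and 6 fell, with Irak4 at 0.55 and Nfkb1 at 0.76, opposite in 1 other probe. MHC class I had 3 of 18 higher and 7 lower, with Psmb9 at 0.41 and B2m at -0.35, which with the tissue channel alone were -0.06 and 0.44. MHC class II had 4 of 13 lower, with Lgmn at -0.61 and Cd74 at -0.52, the latter 0.70 with the tissue channel alone. Lymphoid follicle genes had 1 of 15 higher and 1 lower. Chst4 was 0.55, but 0.36 with processed signals (adjusted p = 0.217) and with the repaired background and equal scaling (0.0999). Ccl20 was -0.65, not past the threshold without CV basal 1 (adjusted p = 0.0539) or GF basal 1, 5 or 6 (0.055, 0.0656 and 0.0573). Adjusted over the list alone, 6 T and NK, 5 B and plasma, 10 mast cell, 7 cytokine, 10 Toll-like receptor, 10 MHC class I, 2 MHC class II and 1 lymphoid follicle genes passed.

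Of 8 genes of short-chain fatty acid uptake and sensing 3 rose and 2 fell, with the receptor Olr59 at 0.32 and the transporter partner Bsg at -0.41, which was 0.76 with the tissue channel alone. Fatty acid oxidation had 11 of 36 higher and 4 lower, with Hadh at 0.55 and Acadsb at -0.94 (0.05 with the tissue channel alone). Of 38 genes of the TCA cycle and oxidative phosphorylation 10 rose and 5 fell, with Sdhc at 0.54 and Cox5b at -0.40 (0.39 with the tissue channel alone). Amino acid and polyamine metabolism had 4 of 29 higher and 10 lower, including Bcat1 (-0.70; 0.01 with the tissue channel alone). Stem cell and Wnt genes had 5 of 27 higher and 10 lower, with Nkd1 at -0.60 and Lrig1 at -0.68. Of 22 junction genes 4 rose, including Tjp1 (0.44), and 7 fell, including F11r (-0.41). Clock genes had 3 of 19 lower, with Csnk1d at -0.31 and Rora at -0.20 (0.33 with the tissue channel alone, and not past the threshold without CV basal 2, CV basal 6 or GF basal 6, at adjusted p = 0.0706, 0.0633 and 0.0933). Immediate early and heat shock genes had 5 of 25 lower, with Junb at -0.67 and Hspb1 at -0.86 (0.52 with the tissue channel alone). Endoplasmic reticulum (ER) stress genes had 4 of 25 higher, including Canx (0.40), and 5 lower, including Sel1l (-0.29; 0.07 with the tissue channel alone). Adipocyte genes had 2 of 23 higher and 7 lower, with Adrb3 at -0.47 and Plin1 at least 1.14-fold lower, both not past the threshold with the tissue channel alone (adjusted p = 0.0649 and 0.0812). Exocrine pancreas genes had 3 of 15 higher and 2 lower, with Cel at 0.24 and Ctrb1 at 0.35 (-0.60 with the tissue channel alone). Of 12 colon position genes 5 rose and 3 fell, with Hoxb6 at 2.05. Adjusted over the list alone, 5 short-chain fatty acid, 15 fatty acid oxidation, 15 TCA cycle, 14 amino acid, 15 stem cell, 11 junction, 1 clock, 5 immediate early, 7 ER stress, 7 adipocyte, 5 pancreas and 8 position genes passed.

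**Figure D1:**
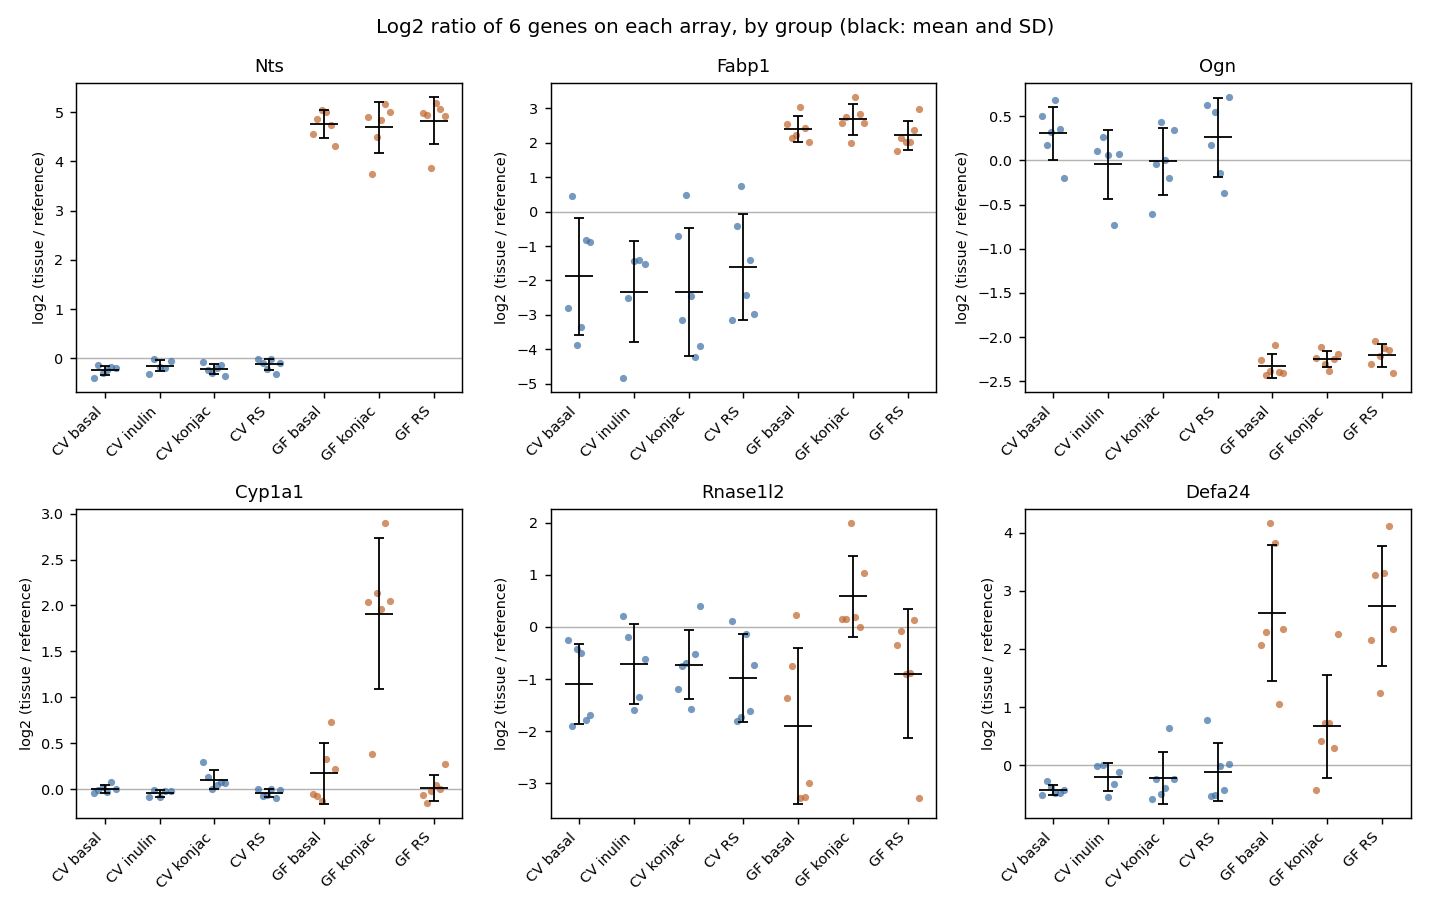
Log2 ratio of tissue over reference (y axis) of Nts, Fabp1, Ogn, Cyp1a1, Rnase1l2 and Defa24 in each array (points) by group (x axis), with mean and SD. Nts averaged 4.75 in GF basal arrays and -0.24 in CV basal arrays, which were not well above background.

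GF and CV rats were also compared on konjac and on RS. On konjac, GF rats had higher Fabp1 (5.00, SE 0.70), Cyp4f1 (4.81, SE 1.12) and Hsd17b6 (3.80, SE 0.49). Hbb (-4.14, SE 0.39), RT1-Bb (-3.98, SE 1.19), Hbb-b1 (-2.68, SE 0.39) and Ogn (-2.24, SE 0.17) were lower. Nts was again higher on both diets, with CV arrays not well above background. On RS, Cyp4f1 (4.11, SE 1.12), Fabp1 (3.82, SE 0.70) and RatNP-3b (3.61, SE 0.29) were higher, while Hbb (-4.58, SE 0.39), Hbb-b1 (-3.43, SE 0.39), RT1-Bb (-2.96, SE 1.19) and the alpha globin Hba-a3 (-2.56, SE 0.37) were lower. On RS, Cyp4f1 gave 2.49 (adjusted p = 0.181) without the arrays with a displaced fit. RT1-Bb on RS was beyond all CV arrays in 4 of 6 GF arrays (adjusted p = 0.0424) and opposite in 1 other probe, and lost its call with processed signals (0.0692) and the tissue channel alone (0.167) and without any of CV RS 1, 3, 4, 5 and 6 and GF RS 1, 2, 4 and 5 (up to 0.101 without GF RS 2).

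With limma, 12136 genes passed on konjac (5821 higher, 6315 lower) and 11101 on RS (5640 higher, 5461 lower). Fibroblast and matrix genes fell in 27 of 29 cases on each diet (adjusted p = 1.2e-14 on konjac and 1.33e-16 on RS; adjusted p = 0.398 and 0.163 with an estimated correlation). Smooth muscle genes fell in 18 of 25 cases on konjac (adjusted p = 5.32e-09) and 23 on RS (adjusted p = 4.15e-16), with adjusted p = 0.518 and 0.163 with an estimated correlation. Enteroendocrine genes rose in 18 of 30 cases on each diet, with 4 lower on konjac and 1 lower on RS (adjusted p = 0.000248 and 0.00122; adjusted p = 0.518 and 0.625 with an estimated correlation). Xenobiotic metabolism had 23 of 52 genes higher on each diet, with 7 lower on konjac and 3 on RS (adjusted p = 0.00902 and 0.0101; adjusted p = 0.518 and 0.625 with an estimated correlation).

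Macrophage genes fell in 16 of 22 cases on konjac and 8 on RS (adjusted p = 0.000228 and 0.0479), and endothelial genes in 9 of 18 and 8 of 18 with 1 higher each (adjusted p = 0.0315 and 0.02). On konjac, MHC class II genes fell in 6 of 13 cases (adjusted p = 0.0315), and mast cell and eosinophil genes rose in 8 of 17 with 1 lower (adjusted p = 0.0411). These konjac lists had adjusted p = 0.518 with an estimated correlation. On RS, interferon genes rose in 17 of 33 cases with 1 lower (adjusted p = 0.00178), cholesterol synthesis in 8 of 25 with 3 passing when adjusted over the list alone (adjusted p = 0.0384), and red blood cell genes fell in 6 of 8 (adjusted p = 0.00135). With an estimated correlation the RS values were adjusted p = 0.625 for interferon and endothelium, 0.881 for macrophages and cholesterol and 0.408 for red cells. Nutrient and bile acid transporters on RS had 11 of 25 higher and 2 lower (adjusted p = 0.00821, and 0.0396 with an estimated correlation). With the tissue channel alone, fibroblast genes on konjac and fibroblast and smooth muscle genes on RS kept the call, and the other lists had adjusted p = 0.123 to 0.886 on konjac and 0.0518 to 0.439 on RS, transporters among them at 0.114. Adjusted over the list alone, 28 fibroblast, 18 smooth muscle, 23 enteroendocrine, 30 xenobiotic, 16 macrophage, 10 endothelial, 6 MHC class II and 10 mast cell genes passed on konjac. On RS these were 27 fibroblast, 24 smooth muscle, 22 enteroendocrine, 26 xenobiotic, 8 macrophage, 9 endothelial, 18 interferon, 6 red cell and 17 transporter genes.

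Inulin, a fructan, was compared with the basal diet in CV rats to ask how it changes the colon when bacteria are present. Rps6ka3, a growth-signal kinase, was higher by 0.35 (SE 0.06), at 0.06 ± 0.09 (SD, n = 5) against -0.29 ± 0.07 (SD, n = 6). The histone acetyltransferase Kat6a was lower by 0.56 (SE 0.09), at 0.10 ± 0.12 against 0.66 ± 0.07, although 1 other probe of Kat6a had the opposite sign. Both cytosolic Hsp90 chaperone genes fell, Hsp90ab1 by 0.50 (SE 0.09) and Hsp90aa1 by 0.45 (SE 0.10). Lgals1, a galectin of muscle and stroma, fell by 0.54 (SE 0.11). The smooth muscle list was lower with camera (adjusted p = 3.82e-17), with 0 of 25 members past the threshold over all genes, and gave adjusted p = 0.239 with an estimated correlation.

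Of 26607 genes, 76 passed with limma, 26 higher and 50 lower, and 4 of them differed at least 1.5-fold. Higher genes were the uridine phosphorylase Upp1 (0.54), Lypd3 (0.53, adjusted p = 0.0219), the inositol monophosphatase Impa2 (0.49, adjusted p = 0.0142), Gpatch1 (0.28), Smim29 (0.27), Azi2 (0.26) and the kinase Mapk9 (0.23), with 1 opposite other probe each for Gpatch1 and Azi2. Lower genes were the ER membrane protein gene Ckap4 (-0.63, adjusted p = 0.0348), the potassium channel Kcnj12 (-0.59, adjusted p = 0.0129), Mfsd6 (-0.59) and Anp32b (-0.45, adjusted p = 0.012). Each gene named in this paragraph lay on the stated side of the basal mean in 5 of 5 inulin arrays. The probes lie on chromosome X at 56776363 to 56776422 (Rps6ka3) and on chromosome 16 at 73559355 to 73559414 (Kat6a) of rn3.

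Of 25 smooth muscle genes 0 passed over all genes and 16 were lower when adjusted over the list alone, with a median of -0.35; Tagln was -0.41 (adjusted p = 0.0577) and Csrp1 -0.43 (adjusted p = 0.069). The list passed with camera at adjusted p = 3.82e-17, but did not pass with an estimated correlation (adjusted p = 0.239). Its mean was lower with inulin on 5 of 5 slides that held both groups, by -0.43 to -0.15. ER stress genes had 5 of 25 lower when adjusted over the list alone (adjusted p = 3.53e-06; adjusted p = 0.324 with an estimated correlation), with the chaperone Dnajc3 at -0.34 and Ddit3 at -0.21. Of 30 enteroendocrine genes 29 had negative values, for example Scg2 (-0.30) and Pcsk2 (-0.22), with adjusted p = 2.76e-05 and 0.632 with an estimated correlation. The mean of that list was lower on 3 of 5 slides (-0.75 to 0.13). Within the basal group it was highest in CV basal 2 (0.33) and CV basal 6 (0.17). These arrays had the lowest means of the colon position list (-0.59 and -0.58), which mixes proximal and distal markers and gives no place along the colon. Neuron and glia genes had 4 of 27 lower when adjusted over the list alone (adjusted p = 0.000118; adjusted p = 0.715 with an estimated correlation), with Uchl1 at -0.32 and Syt1 at -0.23. Fibroblast genes had a median of -0.19 (adjusted p = 0.000397; adjusted p = 0.834 with an estimated correlation), with Sparc at -0.36 and Dcn at -0.46, and gave adjusted p = 0.127 without CV inulin 4.

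Stem cell and Wnt genes (median -0.09; Axin2 -0.33, Dkk3 -0.34) and adipocyte genes (median -0.15; Adrb3 -0.22, Pparg -0.44) passed downward at adjusted p = 0.0306 and 0.0495. Fatty acid oxidation (median 0.05; Acot2 0.31, Hadha 0.32, the latter opposite in 1 other probe) and exocrine pancreas genes (median 0.08; Sycn 0.16, Cela1 0.76) passed upward at adjusted p = 0.03 and 0.00502. With an estimated correlation the adjusted p was 0.632, 0.93, 0.834 and 0.239 in that order. Of pancreas genes 1 passed when adjusted over the list alone, and 0 of the stem cell, adipocyte, fatty acid oxidation, enteroendocrine and fibroblast lists. Fitting the compared groups alone left 3 genes and slide as a fixed block 12, and array weights gave 1677. CV inulin 2 and 5 had a displaced background fit and shrunken ratios, and no CV basal array did. The weights gave CV inulin 5 the highest value of all arrays (3.43), so the count of 1677 leans on an array with shrunken ratios. A smooth muscle covariate left 0 with limma, with 1203 genes at unadjusted p under 0.05, against 2837 in the fit without it. The count was 45 without CV basal 1, 46 without CV basal 2, 146 without CV basal 3, 34 without CV basal 4, 41 without CV basal 6 and 13 without CV inulin 5.

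Konjac, a glucomannan, was compared with the basal diet in CV rats. No gene passed with limma (0 of 26607, with 1803 at unadjusted p under 0.05). The genes with the smallest p were Anp32b (-0.45, SE 0.08, adjusted p = 0.0715), the sodium-potassium-chloride cotransporter Slc12a2 (-0.46, SE 0.09, adjusted p = 0.0811) and Utp14a (-0.23, SE 0.05, adjusted p = 0.0811, opposite in 1 other probe). Cell cycle genes were lower as a group, with 41 of 42 negative and a median of -0.14, for example Cenpf (-0.40) and Rrm1 (-0.28). The cell cycle list passed with camera at adjusted p = 0.000114, against adjusted p = 0.968 with an estimated correlation and 0.511 without CV konjac 3.

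ER stress genes (median -0.16, with Dnajc3 at -0.29 and Dnajb9 at -0.17) passed downward with camera at adjusted p = 8.59e-05. They did not pass with an estimated correlation (adjusted p = 0.744). Enteroendocrine genes (median -0.10; Scg2 -0.32, Sst -0.40), TCA cycle genes (median -0.08; Atp5f1c -0.14, Ndufs3 -0.14) and smooth muscle genes (median -0.10; Rgs5 -0.40, Kcnmb1 -0.12) passed downward at adjusted p = 0.00148, 0.0137 and 0.0391, each with adjusted p = 0.968 with an estimated correlation. Stem cell and Wnt genes (median -0.11; Dkk3 -0.22, Bmi1 -0.15) passed downward and exocrine pancreas genes (median 0.06; Sycn 0.11, Amy2 0.39) upward, at adjusted p = 0.0239 and 0.0391, both with adjusted p = 0.744 with an estimated correlation. Array weights gave 55 genes, the count was 5 without CV basal 3, 3 without CV konjac 1 and 1 without CV basal 2.

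RS was compared with the basal diet in CV rats. No gene passed with limma (0 of 26607, with 2611 at unadjusted p under 0.05). The genes with the smallest p were the collagen Col27a1 (-0.38, SE 0.07, adjusted p = 0.0961), Utp14a (-0.24, SE 0.05, adjusted p = 0.0961) and the autophagy gene Atg3 (-0.28, SE 0.06, adjusted p = 0.131). Smooth muscle genes were lower as a group, 15 of 25 when adjusted over the list alone, with a median of -0.26, the smooth muscle myosin Myh11 at -0.48 and Smtn at -0.41. That list passed with camera at adjusted p = 3.4e-12, but did not pass with an estimated correlation (adjusted p = 0.726). Its mean was lower on 5 of 6 slides.

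Neuron and glia genes (3 of 27 lower when adjusted over the list alone; Uchl1 -0.36, Tubb3 -0.23), ER stress genes (median -0.13; Manf -0.29, Ddit3 -0.13) and red blood cell genes (median 0.19; Hbb-b1 1.01, Ahsp 0.44) passed at adjusted p = 0.00372, 0.011 and 0.00731, each with adjusted p = 0.726 with an estimated correlation. Adipocyte genes (median -0.17; Dgat2 -0.49, Acaca -0.36, the latter opposite in 1 other probe), enteroendocrine genes (median -0.07; Cpe -0.37, Scg2 -0.26) and TCA cycle genes (median -0.08; Cox4i1 -0.27, Ndufa9 -0.19, the latter opposite in 1 other probe) passed at adjusted p = 0.0382, 0.0382 and 0.0256, each with adjusted p = 0.914 with an estimated correlation. Cpe was 0.06 without the arrays with a displaced background fit, and the TCA list gave adjusted p = 0.734 in the opposite direction without CV RS 1, one of those arrays. Array weights gave 506 genes, with a high weight of 2.53 for CV RS 6, an array with a displaced background fit. The count was 138 without CV RS 2, 5 without CV basal 5 and 1 without CV basal 3.

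Konjac was compared with the basal diet in GF rats to ask what it does when no bacteria can ferment it. Cyp1a1, the cytochrome induced through the aryl hydrocarbon receptor, was higher by 1.74 (SE 0.19, adjusted p = 1.63e-06), at 1.91 ± 0.83 (SD, n = 6) against 0.17 ± 0.33 (SD, n = 6), and lay above all basal arrays in 5 of 6. The pancreatic-type ribonuclease genes Rnase1l2 (2.49, SE 0.54) and Rnase1l1 (1.21, SE 0.24) rose. Defa24 fell by 1.96 (SE 0.41), at 0.66 ± 0.88 against 2.63 ± 1.17, and RatNP-3b fell by 1.21 (SE 0.29). The smooth muscle list rose as a group, with 7 of 25 members past the threshold. Lower genes included Baat, which conjugates bile acids, by 1.04 (SE 0.18), the bile acid transporter Slc10a2 by 0.96 (SE 0.19), Ugt2b1 by 1.25 (SE 0.19) and Cyp3a18 by 1.18 (SE 0.19).

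Of 26607 genes, 271 passed with limma, 213 higher and 58 lower, and 51 differed at least 1.5-fold. Further rises were those of the amino acid transporter Slc38a4 (1.15), the glutathione transferase Gstm1 (0.96), the interleukin 1 decoy receptor Il1r2 (0.90), the trefoil peptide Tff1 (0.86) and Nptx2 (0.84). Further falls were those of the lectin Colec10 (-1.32) and Slc13a1 (-1.16). Rnase1l2 lay above all basal arrays in 2 of 6 konjac arrays and above their mean in 6. On the 2 slides that held both groups it rose by 0.40 and 1.52 and Rnase1l1 by 0.20 and 0.84, while Slc38a4 rose on 1 (-0.57 and 1.03). Among GF basal arrays Rnase1l2 was lowest in GF basal 4, 5 and 6 (-3.28, -3.26 and -3.00), which shared a slide with GF RS 5 (0.13) and with no konjac array. GF RS 6 was as low (-3.29), on a slide it shared with GF konjac 6 (1.03). The Cyp1a1 probe lies on chromosome 8 at 61487187 to 61487246 and the Ugt2b1 probe on chromosome 14 at 22650838 to 22650897 of rn3.

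Of 25 smooth muscle genes 7 rose and 18 rose when adjusted over the list alone, with a median of 0.39, among them Casq2 (0.68), Synm (0.66), desmin, Des (0.55) and Ppp1r14a (0.40). The list passed with camera at adjusted p = 1.55e-22, and at adjusted p = 0.0495 with an estimated correlation. Its mean was higher on both slides that held the 2 groups, by 0.28 to 0.46. Mast cell genes rose in 2 of 17 cases, Mcpt3 (0.78) and histidine decarboxylase, Hdc (0.54), and mucus genes in 2 of 32, Tff1 and Sytl2 (0.47); the lists had adjusted p = 0.00124 and 0.00177, and adjusted p = 0.386 with an estimated correlation. Nutrient and bile acid transporters had 1 of 25 higher, Slc38a4, and 2 lower, Slc10a2 and Slc7a9 (-0.69), and passed downward at adjusted p = 0.00856 and at 0.035 with an estimated correlation. Neuron and glia genes rose in 1 of 27 cases, the neurofilament Nefh (0.26), with adjusted p = 0.000961 and 0.664 with an estimated correlation. When adjusted over the list alone, 6 mast cell, 4 mucus, 7 transporter and 1 neuron genes passed.

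Another 3 lists passed downward with no member past the threshold: MHC class II (Ctss -0.18, RT1-Da -0.24; adjusted p = 0.0404, and 0.664 with an estimated correlation), macrophages (Cd163 -0.20, Fcgr3a -0.27; adjusted p = 0.0234) and ion and water transport (Scnn1g -1.38, Slc12a2 -0.22; adjusted p = 0.0344), the latter 2 with adjusted p = 0.769 with an estimated correlation. Xenobiotic metabolism did not pass as a list (adjusted p = 0.313), with Cyp1a1, Gstm1 and Tiparp (0.36) higher and Cyp3a18 lower. Single rises outside the called lists were those of the antimicrobial Camp (0.59), Gata3 (0.55) and Nkg7 (0.64). Slide as a fixed block left 20 genes, with Cyp1a1 at 1.41 (adjusted p = 0.0878), processed signals 39, the tissue channel alone 76 and a smooth muscle covariate 5, while fitting the compared groups alone gave 638 and array weights 769. The count was 162 without GF basal 1, 508 without GF basal 2, 105 without GF basal 4, 140 without GF basal 5, 161 without GF basal 6, 153 without GF konjac 1, 147 without GF konjac 3, 169 without GF konjac 5 and 145 without GF konjac 6.

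**Figure D2:**
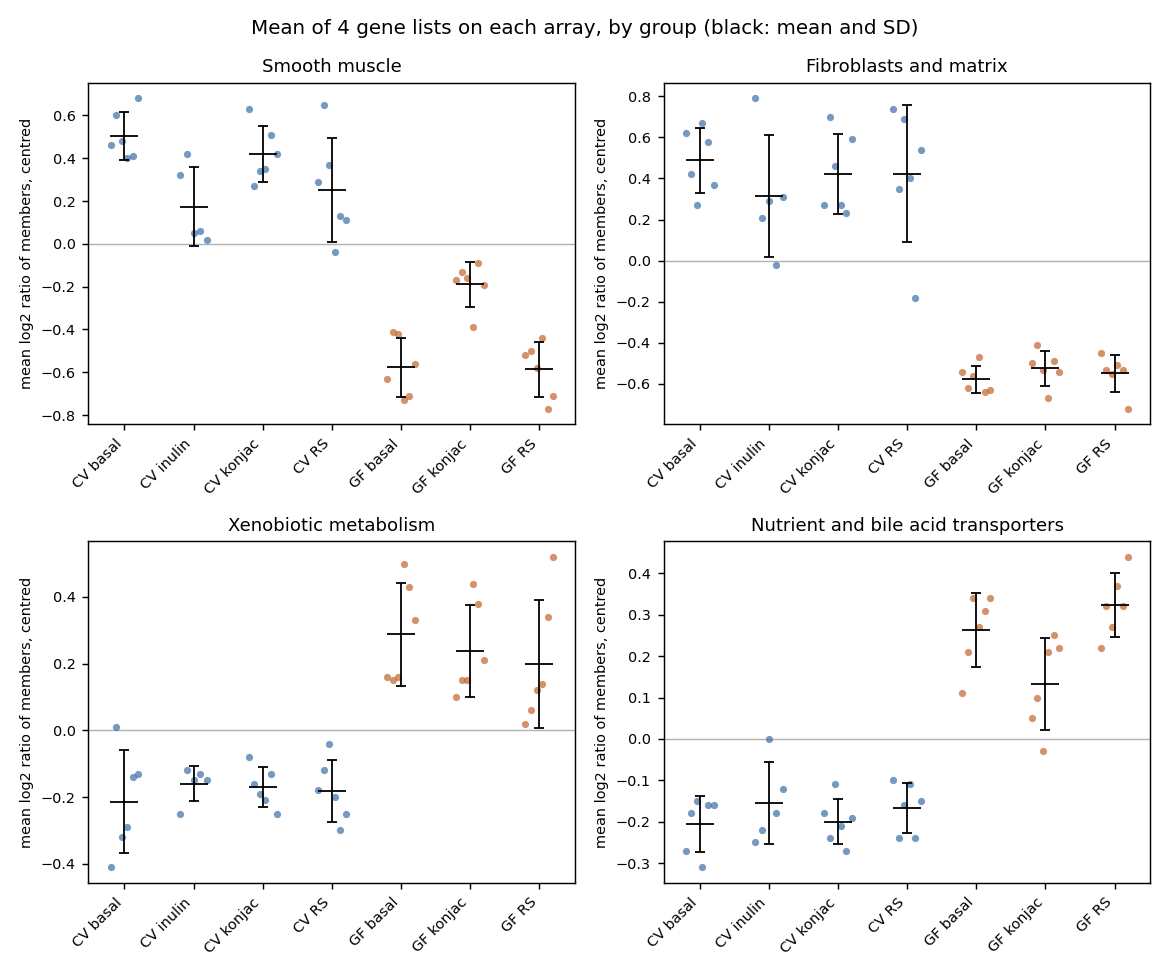
Mean log2 ratio of the genes of 4 lists (y axis) in each array (points) by group (x axis), with mean and SD. The smooth muscle mean was -0.19 ± 0.11 in GF konjac arrays and -0.57 ± 0.14 in GF basal arrays.

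RS was compared with the basal diet in GF rats. No gene passed with limma (0 of 26607, with 942 at unadjusted p under 0.05). The genes with the smallest p were the eosinophil-type ribonuclease Rnase2 (adjusted p = 0.389, basal arrays not well above background), the mucin glycosyltransferase Gcnt4 (-0.20, SE 0.04, adjusted p = 0.415) and the olfactory receptor Or6f2 (0.86, SE 0.21, adjusted p = 0.745). Interferon genes were higher as a group, with 29 of 33 positive, a median of 0.11 and 3 passing when adjusted over the list alone, for example the ubiquitin-like Isg15 (0.55) and Herc6 (0.38). That list passed with camera at adjusted p = 6.2e-09, but did not pass with an estimated correlation (adjusted p = 0.245).

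Lymphoid follicle genes had 0 of 15 positive (Ccl19 -1.28, Tnfsf11 -0.22; adjusted p = 0.0108). Xenobiotic metabolism (Cyp3a18 -0.44, Ugt8 -0.36) and cholesterol synthesis (Stard4 -0.17) passed downward at adjusted p = 0.019 and 0.0473, and MHC class I (Erap1 0.14, B2m 0.14) and neurons (Sncg 0.31) upward at adjusted p = 0.0473 each. With an estimated correlation these 5 lists had adjusted p = 0.935. The cholesterol list gave adjusted p = 0.999 in the opposite direction without GF basal 6. Colon position genes (Hoxb8 -0.43, Hoxb6 -0.26) passed downward with camera at adjusted p = 0.0274, but did not pass with an estimated correlation (adjusted p = 0.245).

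Whether a diet acted differently in GF and CV rats was tested as the difference of the diet effects. For konjac, Cyp1a1 rose more in GF rats by 1.64 (SE 0.27, adjusted p = 0.0149), and the adherens junction gene Ctnna3 by 0.58 (SE 0.11, adjusted p = 0.0331). Chrne, an acetylcholine receptor subunit, went the other way by -0.61 (SE 0.11, adjusted p = 0.029). Whether these genes were well above background in each group was not checked for the interaction. Cyp1a1 lay between -0.10 and 0.29 on the CV arrays, where median tissue signal was 45.7 to 64.6 against 280 to 334 on GF arrays. A konjac effect on it in CV rats may therefore have been missed. Cyp1a1, Ctnna3 and Chrne were the 3 genes past the threshold with limma, against 2323 at unadjusted p under 0.05. Smooth muscle genes differed most among lists, with 21 of 25 higher when adjusted over the list alone and a median of 0.50 (adjusted p = 1.24e-20; adjusted p = 0.14 with an estimated correlation).

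For konjac, ER stress (adjusted p = 9.72e-06), neurons (0.00014), enteroendocrine (0.0018), cell cycle (0.00254), mast cell (0.00573) and mucus (0.0183) lists were higher in the GF effect. Exocrine pancreas (adjusted p = 0.00411), macrophage (0.0142), interferon (0.0362), transporter (0.0362), xenobiotic (0.0424) and MHC class II (0.0443) lists were lower. The xenobiotic list passed in the opposite direction with a smooth muscle covariate (adjusted p = 0.00176). All had adjusted p of 0.14 or more with an estimated correlation. Among these lists, 3 ER stress, 3 enteroendocrine, 3 xenobiotic, 3 transporter, 2 pancreas, 1 neuron and 1 mast cell genes passed when adjusted over the list alone. The count of 3 genes became 139 with array weights, 10 without background correction, 21 without GF konjac 4, 15 without GF konjac 2, 10 without GF basal 3, 9 without GF basal 2, 7 without CV konjac 1 or CV basal 4, 5 without CV basal 1 or CV basal 5, and 1 without any of CV basal 2, CV basal 3, CV konjac 2, CV konjac 4, CV konjac 6, GF basal 4 and GF konjac 3, where Cyp1a1 alone stayed past the threshold. Ctnna3 also fell short without CV konjac 3 (adjusted p = 0.0853), GF basal 1 (0.0526), GF basal 6 (0.0563) or GF konjac 5 (0.0579). With slide as a fixed block the adjusted p was 0.0816 for Cyp1a1 and Chrne and 0.108 for Ctnna3. In a fit of the compared groups alone it was 0.0682 for Cyp1a1 and 0.0637 for Ctnna3.

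For RS, no gene differed between GF and CV rats with limma (0 of 26607, with 874 at unadjusted p under 0.05). Among the smallest p values were those of Snx11 (-0.23, SE 0.06, opposite in 1 other probe) and the adhesion gene L1cam (0.51, SE 0.14), both with adjusted p = 1. Smooth muscle (adjusted p = 1.02e-08), neuron (2.78e-06), adipocyte (0.000649), enteroendocrine (0.00106), interferon (0.00186) and TCA cycle (0.0172) lists were higher in the GF effect. Xenobiotic (adjusted p = 0.00106), lymphoid follicle (0.00186), red cell (0.00342), B and plasma cell (0.0172) and colon position (0.0182) lists were lower. All had adjusted p of 0.479 or more with an estimated correlation, and the TCA list gave adjusted p = 0.91 in the opposite direction without CV RS 1.

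The carbohydrates were compared with each other in CV rats, and 0 genes passed with limma in each of the 3 comparisons, with 505, 743 and 1709 at unadjusted p under 0.05 for inulin against konjac, inulin against RS and konjac against RS. Smooth muscle genes were lower with inulin than with konjac (median -0.24, adjusted p = 1.68e-23; adjusted p = 0.0824 with an estimated correlation) and than with RS (adjusted p = 0.0139; adjusted p = 0.959 with an estimated correlation), and higher with konjac than with RS (median 0.20, adjusted p = 3.63e-07; adjusted p = 0.988 with an estimated correlation). Cell cycle genes were higher with inulin (adjusted p = 0.0002) and with RS (adjusted p = 0.000284) than with konjac, at adjusted p = 0.879 and 0.988 with an estimated correlation.

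Neuron (adjusted p = 0.0002), fibroblast (0.00122), adipocyte (0.00176), macrophage (0.0109) and mast cell (0.0109) lists were lower with inulin than with konjac, each with adjusted p = 0.879 with an estimated correlation. Fibroblast (adjusted p = 0.000642), red cell (0.000642), ER stress (0.00799) and enteroendocrine (0.0108) lists were lower and fatty acid oxidation (0.0241) higher with inulin than with RS, each with adjusted p = 0.959 with an estimated correlation. Adipocyte genes were higher with konjac than with RS (adjusted p = 0.0486; adjusted p = 0.988 with an estimated correlation). The genes with the smallest p were Asnsd1 (0.22), Azi2 (0.19, opposite in 1 other probe) and Sppl2a (-0.34) for inulin against konjac, and Dop1b (0.31), Ptk2b (0.21) and Mettl17 (0.28) for inulin against RS. For konjac against RS they were Dop1b (0.33, adjusted p = 0.256), Ptk2b (0.21) and Dusp5 (0.41). Array weights gave 96 genes for konjac against RS. With p adjusted over the list alone, 1 smooth muscle gene passed for inulin against konjac, 1 red cell gene for inulin against RS and 4 smooth muscle genes for konjac against RS.

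The similarity of diet effects was described across the 26607 genes, which are not independent replicates. In CV rats the inulin and konjac effects had a Pearson correlation of 0.77 (Spearman 0.73), inulin and RS 0.70 (0.70) and konjac and RS 0.55 (0.52). In GF rats konjac and RS had 0.54 (0.56). These pairs share a basal group, and simulated draws with no diet effect reached as high a value in 5, 15, 36 and 46 of 100. The konjac effects in CV and GF rats, which share no control, had -0.01 (0.03), and the RS effects 0.16 (0.26). Over genes past the threshold in either comparison the konjac value was 0.22.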

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

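The tests of the reference channel for GF against CV, all tests of covariates for konjac in GF rats and for inulin in CV rats, the share of a difference kept with the slide as a block, and the fits with repaired or left-out arrays were chosen after the result was seen; the slide block itself was planned. The tests of shrunken ratios and of muscle in GF against CV, and the splits of the samples, were written before.

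The largest pattern was the difference of 12864 genes between GF and CV rats on the basal diet, in which muscle and matrix genes were lower in GF rats. Shrinkage of the CV ratios by their lower signal would move genes further from 0 in GF rats. Of called genes 31% differed in the direction of their CV konjac ratio, as did 10.9% of the 878 with a CV konjac ratio of at least 0.5 either way. This argues against shrinkage as the whole cause. The CV konjac arrays share the session of the CV basal arrays. A bias common to all CV arrays would therefore also lower these shares, even where shrinkage took part. The test thus cannot speak against a part through shrinkage or against other differences between the sessions. A change of the reference between sessions was argued against as the whole cause by a correlation over called genes of 0.016 with the reference channel's difference. The correlation was 0.62 with the difference of the tissue channel, which moved the same way for 73.5% of called genes and for 94.9% of the 633 genes that differed at least 2-fold. The ratio contains the tissue channel, so this agreement is partly built in, more so for genes picked by a large ratio difference. The agreement is therefore no separate evidence against a change of the reference. The ratio subtracts the reference, so a value near 0 also arises when both channels shift together. It does not show that the reference was stable, and a part through the reference stays open. A smaller share of muscle wall in the GF tissue may contribute and cannot be told apart: the differences correlated at -0.231 with the slope on the smooth muscle score within groups, and the score's shift of -1.08 predicted a median size of 0.14 against 0.33 observed. The design names colonisation status as the biological explanation, which session and slide leave untested.

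The next pattern was the 271 genes that differed with konjac in GF rats. Slide layout was argued against as the whole cause, since with the slide as a fixed block the median called gene kept 92.4% of its difference; 20 genes passed, 9 of them shared, with the median size moving from 0.40 to 0.36 and the SE from 0.09 to 0.11. Another sampling time was argued against as the whole cause, with 97.1% kept with the clock gene score and 262 genes passing, 241 of them shared. More muscle wall in the konjac tissue may account for part of the pattern and cannot be told apart, since the median called gene kept 47.1% (quartiles 22.4% to 73.1%) with the smooth muscle score as a covariate. There 5 genes passed, 3 of them shared, because the median size fell from 0.40 to 0.17 while the SE rose from 0.09 to 0.13, and Cyp1a1 stood at 2.07 (SE 0.33, adjusted p = 0.00242 with limma), so an effect of konjac itself stays open.

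The last weighed pattern was the 76 genes that differed with inulin in CV rats. Less muscle wall in the inulin tissue was argued against as the whole cause, since the median called gene kept 80.9% of its difference (quartiles 69.4% to 89.3%) with the smooth muscle score as a covariate. The calls ended there (0 genes passed with limma) because the median size moved from 0.37 to 0.28 and the SE from 0.08 to 0.09, so a part through muscle may remain. Another colon position was argued against with 99.1% kept, and 77 genes passed, 53 of them shared. The background fit was displaced on CV inulin 2 and 5 and on no CV basal array, and 13 genes passed without CV inulin 5. The count rose, however, without background subtraction, with the deposited log2 values and with processed signals, which keep all arrays and do not use that fit. It also rose with the repaired background and equal scaling. It fell without the displaced arrays, which also leaves fewer samples. Counts do not show whether the same genes passed, and the part of the pattern owed to this imbalance was not weighed. An effect of inulin or of its fermentation stays open and was not tested apart.

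For other splits of the same arrays into groups of the same sizes, 100 were counted per comparison, the real one included. Chance could be excluded for GF against CV, where 1 split (the real one) gave as many genes: 12864 on the basal diet against at most 6502 in another split, 12136 on konjac against 7339 and 11101 on RS against 7467. For inulin 2 splits gave as many genes (76 against 94 in the highest other), and for konjac in GF rats 2 did (271 against 286). For the konjac interaction 4 did (3 against 8). These shares lie under the bound set before. In each case, however, another split called more genes than the real one, and the shares were not adjusted over the comparisons. Chance is therefore not excluded for these results. All splits exchange arrays across slides in a fit without slides, so they bear on chance only apart from the slides. With the slide as a block 12 genes passed for inulin and 20 for konjac in GF rats. None of the 3 genes of the konjac interaction did (adjusted p = 0.0816 for Cyp1a1 and Chrne and 0.108 for Ctnna3 with limma). Where no gene passed with limma, all 100 splits necessarily gave as many, so the splits say nothing on chance. The highest other splits there were 3192 for konjac in CV rats, 1042 for RS in CV rats, 323 for RS in GF rats, 29 for the RS interaction, 2178 for inulin against konjac, 1027 for inulin against RS and 1494 for konjac against RS. Splits that call many more genes than the real one point to a structure of the samples. The highest split for inulin against RS put CV RS 1, 4 and 6 with CV inulin 2 and 5, all with a displaced background fit. That for konjac against RS put CV RS 1 and 4 with CV konjac 5, which also had a displaced fit, but not with CV RS 6, which had one too. It added CV konjac 2, 3 and 6, whose fit was not displaced, so it follows the displaced fits only in part. Without the arrays with such a fit, 3 genes passed in each comparison. The highest split for konjac in CV rats put CV konjac 1, 4 and 6 with CV basal 2, 5 and 6, none of them displaced. Of these, CV konjac 1, CV basal 2 and CV basal 6 had the lowest means of the colon position list among the 12 arrays (-0.54, -0.59 and -0.58). They also had the highest enteroendocrine means (0.26, 0.33 and 0.17). The mean of the position list ignores whether a member marks the proximal or the distal colon, so it gives no place along the colon. In GF basal arrays it averaged 0.34 while the signed position score averaged -1.21, and in CV basal arrays -0.32 while the score averaged 0.57.

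Effects that differed between GF and CV rats by the interaction test were those of konjac on Cyp1a1 (1.64), Ctnna3 (0.58) and Chrne (-0.61). Signal over background was not checked for these, and effects on the dimmer CV arrays may have been missed. Gene lists whose konjac effect was higher in GF rats, with camera's adjusted p, were smooth muscle (1.24e-20), ER stress (9.72e-06), neurons and glia (0.00014), enteroendocrine (0.0018), cell cycle (0.00254), mast cells (0.00573) and mucus (0.0183). Lower were exocrine pancreas (0.00411), macrophages (0.0142), interferon (0.0362), transporters (0.0362), xenobiotic metabolism (0.0424) and MHC class II (0.0443), of which xenobiotic metabolism passed in the opposite direction with the smooth muscle score as a covariate (0.00176). For RS the higher lists were smooth muscle (1.02e-08), neurons and glia (2.78e-06), adipocytes (0.000649), enteroendocrine (0.00106), interferon (0.00186) and TCA cycle (0.0172). The lower ones were xenobiotic metabolism (0.00106), lymphoid follicle (0.00186), red cells (0.00342), B and plasma cells (0.0172) and colon position (0.0182). None of these lists passed with an estimated correlation, where the smallest adjusted p was 0.14 for konjac and 0.479 for RS. Single arrays carried several calls, and the highest adjusted p with one array left out was, for konjac, 0.632 for interferon (without GF basal 4), 0.254 for cell cycle (without CV konjac 3), 0.202 for MHC class II (without CV konjac 4), 0.191 for xenobiotic metabolism (without GF basal 4), 0.163 for macrophages (without CV basal 3), 0.125 for mucus (without CV basal 5) and 0.0997 for transporters (without GF basal 3). For RS it was 0.91 for TCA cycle (without CV RS 1), 0.132 for B and plasma cells (without GF RS 6), 0.101 for enteroendocrine (without CV basal 2) and 0.078 for colon position (without GF RS 1).

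An array far from the others of its group was found in 29 of 423 groups tested (list means and the genes with the largest differences or smallest p), where chance gives about 1 in 20. The value given is the gap to the nearest array divided by the range. Among list means, GF konjac 4 was low for smooth muscle (0.653), neurons and glia (0.722) and Toll-like receptor genes (0.635). GF konjac 6 was high for lymphoid follicle genes (0.798) and B and plasma cells (0.66), and GF RS 4 was high for B and plasma cells (0.639). GF basal 4 was high for interferon genes (0.628), GF basal 6 low for fatty acid oxidation (0.66) and GF RS 6 high for cholesterol synthesis (0.68). CV RS 2 was low for MHC class II (0.76) and CV RS 1, an array with a displaced background fit, low for the TCA cycle (0.754). CV basal 1 was high for T and NK cells (0.738), CV inulin 4 high for the cell cycle (0.878) and CV inulin 1 low for xenobiotic metabolism (0.795). CV konjac 1 was high for enteroendocrine genes (0.656) and low for exocrine pancreas genes (0.736), and CV konjac 4 low for neurons and glia (0.792).

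Among genes, RT1-Bb was low in CV basal 5 (0.746) and CV RS 2 (0.714) and high in GF konjac 2 (0.795). On arrays with a displaced background fit, Cyp1a1 was 0.38 in GF konjac 2 against 1.96 to 2.90 in the other 5 (0.626), and Nts was 3.86 in GF RS 3 against 4.92 to 5.18 (0.801). High single values were those of Atg3 in CV basal 4 (0.642), Kcnj12 in CV basal 2 (0.772), Or6f2 in GF basal 1 (0.82), Ptk2b in CV inulin 3 (0.782) and Rnase2 in GF RS 1 (0.641). Low single values were those of L1cam in CV RS 5 (0.719) and Slc10a2 in GF konjac 1 (0.684).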

How the results depend on the processing

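The repaired background fits, the fits without displaced arrays and the fits with covariates were chosen after seeing the data; the other settings were chosen before. Counts are genes past the threshold unless stated, and except where said the cause was not tested. Counts for GF against CV stayed within 1.5 times their reported values in all settings but the fold minimum and, on RS, the tissue channel alone. Aquantile scaling leaves the ratios as they are, so it tested nothing here. Signal over background limits dim genes: the CV arrays had a median tissue signal of 45.7 to 64.6 above backgrounds of 38 to 43.

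A minimum of 1.5-fold, which only removes genes, left 2357, 1965 and 1847 for GF against CV on basal, konjac and RS, 4 for inulin and 51 for GF konjac. No background subtraction gave 244 for inulin, 6 for CV konjac, 142 for GF konjac, 10 for the konjac interaction, 1 for inulin against konjac and 8 for inulin against RS. The deposited matrix gave 246, 6, 141, 10, 1 and 8 in that order. Processed signals gave 174 for inulin, 5 for CV konjac and 39 for GF konjac. The tissue channel alone gave 17851 for GF against CV on RS, 142 for inulin, 12 for CV konjac, 76 for GF konjac and 6 for inulin against RS. Without a filter inulin had 45. With the strict filter CV konjac had 1, GF konjac 170 and the konjac interaction 1. The mean of probes gave 4 for CV konjac, and trended robust moderation 46 for inulin. Array weights gave 1677 for inulin, 55 for CV konjac, 506 for CV RS, 769 for GF konjac, 139 for the konjac interaction and 96 for konjac against RS. The highest weights were those of CV inulin 5 (3.43) and CV RS 6 (2.53), both with a displaced background fit.

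The compared groups alone gave 3 for inulin and 638 for GF konjac. Slide as a fixed block gave 12 for inulin and 20 for GF konjac, and slide as a random block (correlation 0.008) 1 for CV konjac. The replicate number as a block, which for CV arrays is the slide block again, gave 12 for inulin, 522 for GF konjac and 11 for the konjac interaction. Leaving out spots far below background gave 3 for CV konjac, 17 for the konjac interaction and 4 for inulin against RS. With equal scaling added, inulin had 455, CV konjac 25, GF konjac 56, the konjac interaction 9 and inulin against RS 8. Leaving out the displaced arrays, which also leaves fewer samples, gave 11 for inulin, 1 for CV konjac, 2 for CV RS, 14 for the konjac interaction, 1 for the RS interaction, 2 for inulin against konjac, 3 for inulin against RS and 3 for konjac against RS. The position covariate gave 1 for CV konjac. The muscle covariate gave 0 for inulin and 5 for GF konjac. The clock covariate gave 299 for inulin, 17 for CV konjac and 8 for CV RS.

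Of 105 gene lists called, 4 passed with an estimated correlation, and 58 to 111 in the other settings. Over called genes alone the correlations of diet effects were 0.96 for inulin and konjac, 0.95 for inulin and RS and 0.68 for konjac and RS in GF rats, and konjac in CV and GF rats turned to 0.22. The first 3 pairs share a basal group, and the choice of called genes may raise their values further, for which no simulated draws were made.

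Leaving out each array in turn gave 12087 to 12714, 10932 to 12281 and 10029 to 11320 for GF against CV on basal, konjac and RS. It gave 13 (without CV inulin 5) to 146 (without CV basal 3) for inulin, 0 to 5 (without CV basal 3) for CV konjac and 0 to 138 (without CV RS 2) for CV RS. GF konjac had 105 (without GF basal 4) to 508 (without GF basal 2) and the konjac interaction 1 to 21 (without GF konjac 4). RS in GF rats, the RS interaction and the carbohydrates against each other stayed at 0 to 0 with limma. Gene lists numbered 19 to 58, counted over the comparisons that hold the left-out array.

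Among the genes named in the report for GF against CV on the basal diet, signs that turned with the tissue channel alone were those of Rig1 (0.72), Psmb9 (-0.06), B2m (0.44), Cd74 (0.70), Icos (0.45), Bsg (0.76), Acadsb (0.05), Cox5b (0.39), Mvk (-0.18), Creb3l1 (0.46), Rora (0.33), Hspb1 (0.52), Sel1l (0.07), Uchl1 (0.12), Vwf (0.04), Ctrb1 (-0.60) and Bcat1 (0.01). Without the displaced arrays Cpe turned to 0.06 with RS in CV rats, and with the muscle covariate Cd163 to 0.00 with konjac in GF rats.

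List tests that turned direction, with their adjusted p, were TCA cycle without CV RS 1 and cholesterol without GF basal 6. With each array left out in turn these ranged from 0.00107 to 0.734 for TCA cycle in CV RS, from 0.000881 to 0.91 for TCA cycle in the RS interaction and from 0.00102 to 0.999 for cholesterol in GF RS. Without the displaced arrays these were TCA cycle for the RS interaction (0.98), and fatty acid oxidation (0.0696) and fibroblasts (0.501) for inulin against RS. With the position covariate it was enteroendocrine genes for inulin against RS (0.577). With the muscle covariate, built from the smooth muscle list itself, smooth muscle turned for CV konjac (0.939), GF konjac (0.681), the konjac interaction (0.758) and inulin against RS (0.899). It also turned enteroendocrine genes for CV RS (0.663), ion transport (0.68) and neurons (0.0625) for GF konjac, xenobiotic metabolism (0.00176) and neurons (0.425) for the konjac interaction and B cells for the RS interaction (0.967).

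Over the settings that kept all replicates, named genes kept direction and side of the threshold in 1239 of 1283 values for GF against CV on the basal diet, 541 of 679 for inulin (108 lost and 30 gained the call) and 538 of 685 for GF konjac (143 lost, 3 gained). With one array left out these were 955 of 972, 302 of 374 and 363 of 420. List tests kept both in 103 of 144, 138 of 180 and 142 of 160 values in the same order.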

Other observations

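The tests of receptor targets were chosen after the result was seen, and that of colon position was written before. The features with 2 levels were singled out after their values were seen.

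Hox genes, which set position along the body axis and keep a graded expression along the gut, differed between GF and CV rats in both directions. Of 25 measured on the basal diet, 9 were higher and 7 lower in GF rats with limma. Hoxb6 (2.05), Hoxd13 (1.64) and Hoxb7 (0.72) were higher, as was Hoxb8, whose CV arrays were not well above background, while Hoxa5 (-0.98), Hoxa11 (-0.97) and Hoxa9 (-0.90) were lower. On konjac and RS, Hoxb6 was higher by 1.55 and 1.73 and Hoxa5 lower by 0.95 and 0.76. Hoxd13 did not pass on konjac (0.30, adjusted p = 0.667) or RS (0.93, adjusted p = 0.152). With the tissue channel alone Hoxa3 (-0.28) turned to 1.09 and Hoxc6 (0.32) to -0.04.

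Among the 23 CV arrays 13 features lay at 2 levels, with a gap of at least 1.5. RT1-Bb (gap 3.32) and Atp12a, a proton-potassium pump of the distal colon (gap 2.90), each had 5 low and 18 high. In GF arrays RT1-Bb spanned both (-5.99 to -0.23). Others included the glycosyltransferase B3gnt7 (2.36), the surfactant lectin Sftpd (2.14), Tgm3 (1.94), Fxyd4 (1.78), Fam111a (1.70) and the adipokine Adipoq (1.62).

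That the GF tissue was taken nearer to the caecum is a candidate explanation of the Hox differences. It stays open. The colon position score (Hoxd13 and Hoxb13 minus Osr2 and Hoxb6) is built from genes of the pattern, so its own shift was not used. The GF minus CV differences correlated at -0.087 over called genes with the slopes on that score within groups. With slopes from CV arrays alone the correlation was -0.0654, and from GF arrays alone -0.27, where the score varied less (SD 0.24 against 1.09). By the rule written before, which named only the correlation with slopes over all groups, the value of -0.087 counted against the explanation. The demand that slopes from CV and from GF arrays agree was not part of that rule. The value from GF arrays lies on the other side of its bound, so the explanation is left open here.

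Ligands of the aryl hydrocarbon receptor in the konjac diet of the GF rats may account for their higher Cyp1a1, which averaged 0.10 in CV konjac and 0.00 in CV basal arrays. A rise in CV rats may have been missed at the lower tissue signal of their arrays. Of 6 other measured receptor targets 1 passed upward, Tiparp (0.36, adjusted p = 0.0103 with limma), and that count of 1 other receptor target leaves it open. Cyp1b1 (-0.07), Nqo1 (-0.14), Aldh3a1 (-0.03), Ugt1a6 (0.04) and Gsta2 (-0.38) did not pass.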
